A study of Homo sapiens with 3 samples.

How the data were processed

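Total RNA of the HEK293 reporter line was extracted with silica columns, treated with DNase and made into libraries with a ribosomal RNA depletion kit that marks strand, per the labels' protocols. The labels name 1 group of 3 samples. The deposited tables have 3 columns headed with the word mock and a number, a word the labels do not use, so the columns were taken as the 3 replicates of that group without tying a column to a particular sample. The submitters' processing notes name STAR, edgeR, GRCh37 and hg19 without roles or versions. How reads were counted, with which annotation and strand setting, is not given in the sources used here.

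The deposited count table holds whole-number read counts that the authors made for 23436 Entrez genes, not normalized, with a gene width in bases per the file headers. The deposited RPKM table holds values that the authors scaled by that width and by 1 library size per column. Dividing counts by deposited RPKM gave that library size, which was 1.45 times the effective size from the counts in each library. Names came from the RefSeq gene table for GRCh38.p14, which matched 23285 identifiers and left 151 unnamed genes holding 0.223 to 0.227% of the counts. Because the notes name hg19 and the reference at hand was GRCh38, no coordinates were used. That reference served for names, the order of neighbouring genes, GC content and exon lengths (GENCODE 29), which 22651 genes had. Symbols are current ones.

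RPKM was computed from the counts with the deposited width and effective library sizes from edgeR's trimmed mean of M values (factors 1.00, 1.00 and 0.998), so that 1 RPKM here is a lower level on the deposited scale. Each gene's level was tested against 1 RPKM with edgeR 4.0.16 in R 4.3.3 by a quasi-likelihood fit with an intercept only. The package's own F-test does not accept such a model, so the same F statistic was computed from the deviances with the fitted level and with the level held at 1 RPKM. Genes entered if 1 RPKM would give at least 10 counts over the 3 libraries, a rule on length and depth that left 22616 genes. P-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05, for all p-values called adjusted. Pairs were tested by the same method on the counts of both genes, offset by width and library size, with the library as a block, and adjusted over 57 pairs. An exact sign-flip test of 3 libraries cannot go below 0.25. The position of a list is the percentile of its median RPKM among 10000 random lists of the same size, as a description of these libraries. The random lists were drawn in 10 bins of gene length from all genes tested, those below 1 RPKM or without a read included. Differences between libraries were tested by a chi-square test of each gene's 3 counts against the effective library sizes, for genes with a mean of at least 10 counts. For a gene without a read the limit is the RPKM that 3 counts over all libraries would give, and it covers counting error only.

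The level tested, 32 gene lists, the pairs, the tests and most alternatives were fixed before the data were examined. The genes named were fixed by rule: the Polycomb, H3.3, chaperone and reporter host genes of the opening comparisons, the 10 genes with the highest RPKM, the 2 highest and 2 lowest members of each list, and the 10 genes with the largest SD of log2 CPM among those that differed between libraries and had a mean of at least 50 counts. HOXB8, TRIM27, BRD2, TUBB, HSPA1A, HSPA1B, IER3, MTRNR2L1, UBA2, the genes of pairs that changed sign and the members of counts of 5 or fewer were named after their values were seen. The alternatives were DESeq2 1.42.0 size factors, total counts, the DESeq2 Wald test, limma 3.58.1 on the log2 of deposited RPKM plus 0.1 or 1, other filters and levels, pairs without length scaling or block, random lists without length matching, and leaving out each library in turn. GENCODE exon lengths and the deposited library sizes were added after seeing the data.

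On simulated data with known answers, built from the real library sizes, the level test placed 100% of 59 genes set to 0.5 RPKM and 100% of 60 set to 2 RPKM on the right side, 85% of those at 0.8 and 93.3% of those at 1.25, and called 3.33% of those at 1, in a step over 22567 genes. The chi-square test found 92.5% of 200 genes doubled in 1 library and 0.0602% of the others, over 15156 genes. The pair test found 100% of pairs set 1.5-fold apart and 3.45% of equal ones, over 57 pairs. The level and pair simulations took gene lengths as known, with the same spread between libraries for every gene. The chi-square simulation held counting noise only, apart from the doubling. These rates therefore cover no error in gene length and no spread that varies from gene to gene.

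RN7SK, RN7SL1, RN7SL2, the list of mitochondrially encoded genes and the luciferase reporter were not analysed here, and some genes that the rule names are not reported here. Genes with near-identical copies (HSPA1A and HSPA1B, histone genes, H3.3 genes), overlapping or readthrough genes and antisense genes carry uncertain counts. A gene length is a choice of annotation: the GENCODE exon union of CBX8 is 4164 bases against a deposited width of 1546, and that of ATRX is 19266 against 11307.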

Results

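The transcriptome of 1 group of cells was measured by RNA sequencing of 3 libraries, called library 1, library 2 and library 3 by the numbers in the headings of the deposited tables. The cells were HEK293, an established human embryonic kidney line, carrying a single-copy luciferase reporter with UAS sites (binding sites for GAL4 fusion proteins) in the first intron of NCOA5. The series concerns how the Polycomb protein CBX2 and the repressive complex PRC1 bring DAXX, a chaperone of the histone variant H3.3, to chromatin. Here the RNA data were used to describe which of these factors, and which of their possible target genes, were transcribed in the line. Reads assigned to genes came to 34876663, 41388150 and 43842480 for libraries 1, 2 and 3. No group was set against another. The comparisons were therefore of each gene with a level of 1 RPKM, of related genes with each other, of fixed gene lists with other genes, and of the libraries with each other. Values are mean RPKM ± SD over the 3 libraries (n = 3) unless stated. The labels do not say whether the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

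Of 22616 genes tested, 11877 lay above 1 RPKM and 10206 lay below it, while 533 could not be placed on either side. The genes above the level had a median of 10.2 RPKM, and 574 genes exceeded 100 RPKM. Protein-coding genes were above the level in 11027 of 18798 cases, long noncoding RNA genes in 297 of 1929 and small nucleolar RNA genes in 101 of 179. The highest level belonged to RMRP, the RNA of the ribonuclease MRP, at 3577 ± 756 RPKM. It was followed by TMSB10, which encodes an actin-binding thymosin, at 3168 ± 148, the small nucleolar RNA SNORA24 at 1898 ± 1190 and RPPH1, the RNA of ribonuclease P, at 1801 ± 210. The linker histone gene H1-2 reached 1783 ± 41.7, MIR3609 1623 ± 378, the ribosomal protein gene RPS4X 1615 ± 24.0, the actin gene ACTG1 1460 ± 66.8 and the histone gene H2BC11 1342 ± 199. MIR3609, at a width of 80 bases, was too short to enter the level test. Levels rest on the deposited gene widths, and on GENCODE exon lengths RPS4X came to 827 ± 12.3 and H2BC11 to 680 ± 101 RPKM. The 10 genes with the most reads took 2.54 to 2.59% of the counts of a library. NCOA5 (Entrez gene 57727), the host gene of the reporter, stood at 16.6 ± 0.45 RPKM from 7419 reads.

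Among the chromodomain subunits of canonical PRC1, which bind trimethylated lysine 27 of histone H3, 4 of 5 genes were above 1 RPKM and 1 was below. CBX2 (Entrez gene 84733) stood at 12.3 ± 0.78 RPKM, CBX6 at 11.2 ± 0.17 and CBX8 at 10.5 ± 0.52, and on GENCODE lengths at 10.8 ± 0.68, 7.23 ± 0.11 and 3.89 ± 0.19. CBX7 was the member below the level, at 0.533 ± 0.098. CBX2 exceeded CBX7 by 4.53 on the log2 scale (SD 0.17, adjusted p = 1.76e-08, higher in 3 of 3 libraries). On the deposited widths CBX2 and CBX6 lay close together, with a log2 ratio of 0.14 (SD 0.07, adjusted p = 0.0241), a call that was lost without library 2 or library 3 and with no scaling by gene length. On GENCODE lengths CBX2 exceeded CBX6 by 0.58 (adjusted p = 1.93e-05) and CBX8 by 1.48 (adjusted p = 1.75e-06) on the log2 scale. The median of the CBX list, 11.2 RPKM, lay at the 87.0 percentile of random lists of genes of like length. Those lists also hold genes below 1 RPKM, while the genes above it had a median of 10.2 RPKM. A high percentile can therefore mean no more than that the members were expressed.

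All 6 PCGF genes, whose products define the PRC1 subtypes, were above 1 RPKM, with their median at the 94.5 percentile. BMI1, the fourth of the family and part of canonical PRC1, was highest at 26.1 ± 0.99 RPKM, followed by PCGF6 at 18.3 ± 1.23, PCGF5 at 16.4 ± 0.89, PCGF3 at 11.6 ± 0.69 and PCGF1 at 11.2 ± 0.35, which came to 4.80 ± 0.15 on its GENCODE length. PCGF2, the other canonical member, was lowest at 2.90 ± 0.11, with a log2 ratio to BMI1 of -3.17 (SD 0.01, adjusted p = 1.42e-08, lower in 3 of 3 libraries). Of the RING ubiquitin ligases and their canonical partners, 7 of 8 genes were above the level, with the median at the 83.4 percentile. RNF2, which encodes the ligase RING1B, stood at 17.9 ± 0.24 RPKM, SCML1 at 13.3 ± 0.55, PHC2 at 7.63 ± 0.10, PHC1 at 5.35 ± 0.11 and PHC3 at 3.79 ± 0.14. Its paralog RING1 stood at 1.07 ± 0.06 on the deposited gene width and could not be placed on either side of 1 RPKM (adjusted p = 0.0617). That width is 15144 bases against a GENCODE exon length of 1818, on which RING1 came to 8.93 ± 0.53 RPKM and was above the level. RING1 was below RNF2 under both lengths, with log2 ratios of -4.06 (SD 0.07, adjusted p = 1.38e-08) and -0.81.

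All 16 genes of the variant PRC1 list were above 1 RPKM, and the list's median of 10.7 RPKM lay at the 97.1 percentile. All genes above the level together had a median of 10.2 RPKM. On GENCODE lengths the list was at the 94.2 percentile and 15 genes were above, and 15 were above with limma on deposited RPKM. The deubiquitinase gene USP7 was highest at 97.7 ± 2.81 RPKM and the E2F partner gene TFDP1 next at 46.4 ± 1.86. FBRSL1 at 1.93 ± 0.12 and BCORL1 at 1.59 ± 0.07 were lowest; FBRSL1 could not be placed on its GENCODE length, nor BCORL1 with limma. RYBP exceeded its paralog YAF2 by 1.82 on the log2 scale (SD 0.04, adjusted p = 5.55e-08, higher in 3 of 3 libraries).

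All 12 genes of PRC2, the complex that methylates lysine 27 of histone H3, were above 1 RPKM, with a median of 15.5 RPKM at the 99.3 percentile and of 10.1 RPKM on GENCODE lengths. With the deposited library sizes, or limma on deposited RPKM, 11 were above and PHF1 could not be placed. EZH2, the catalytic subunit typical of dividing cells, stood at 30.6 ± 0.96 RPKM and its paralog EZH1 at 5.69 ± 0.46, a log2 ratio of EZH1 to EZH2 of -2.43 (SD 0.16, adjusted p = 1.45e-07, lower in 3 of 3 libraries). The core subunits EED and SUZ12 reached 24.7 ± 1.07 and 14.5 ± 0.43, with EED at 10.2 ± 0.44 on its GENCODE length. The histone-binding gene RBBP7 was highest at 71.1 ± 3.1 (31.8 on its GENCODE length) and the accessory subunit MTF2 next at 33.1 ± 0.69, while PHF19 at 2.94 ± 0.30 and PHF1 at 1.54 ± 0.09 were lowest. In the PR-DUB list, which covers the BAP1 deubiquitinase and its partners, 7 of 8 genes were above the level. OGT was highest at 39.0 ± 0.26 RPKM, BAP1 stood at 21.9 ± 0.40, and ASXL3 was below at 0.253 ± 0.016. Of the MBT domain genes 8 of 9 were above and L3MBTL1 was below at 0.460 ± 0.018; on GENCODE lengths 7 were above, and L3MBTL4, at 1.99 ± 0.20 on its width, could not be placed.

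**Figure D1:**
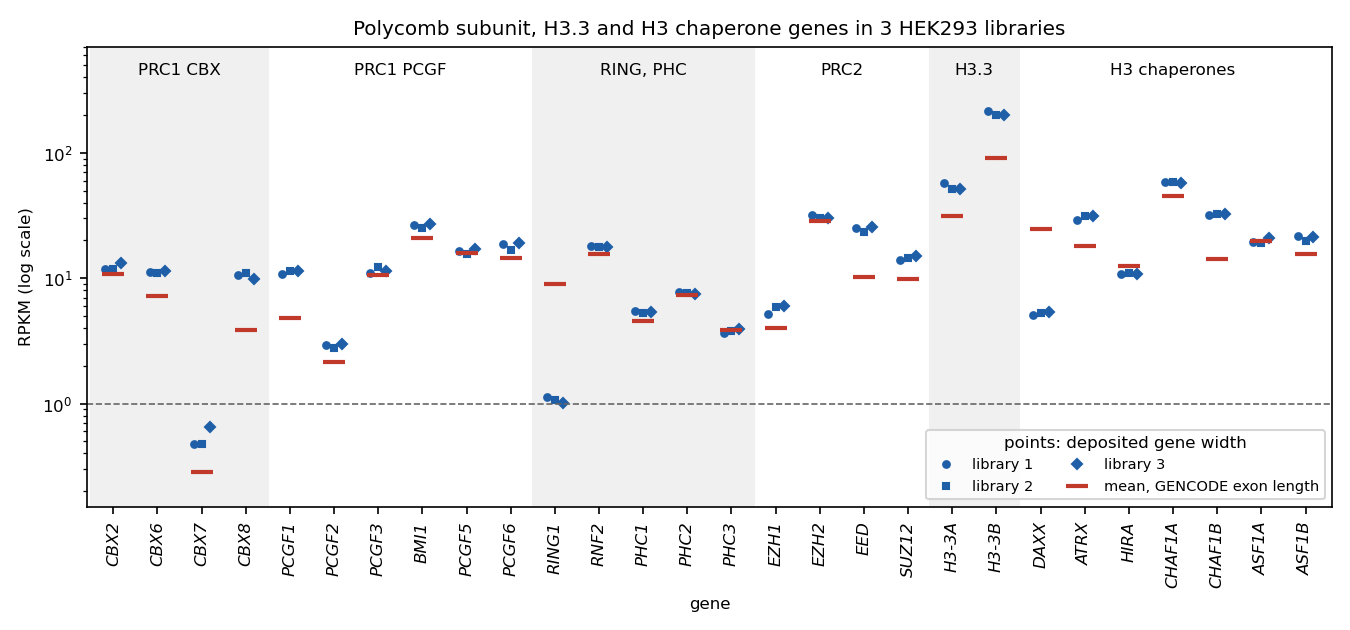
RPKM on a log axis for genes encoding Polycomb subunits, H3.3 and histone H3 chaperones; blue points are libraries 1 to 3 with the deposited gene width, red bars the mean with GENCODE exon lengths and the dashed line 1 RPKM. The libraries lie close together for each gene, and DAXX moves from 5.24 to 24.8 RPKM and RING1 from 1.07 to 8.93 when the length is changed.

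All 3 genes of the H3.3 list, which are H3-3A, H3-3B and the retrocopy H3-5, were above 1 RPKM. H3-3B (H3F3B, Entrez gene 3021) stood at 205 ± 8.45 RPKM and H3-3A (H3F3A, Entrez gene 3020) at 53.4 ± 3.35, a log2 ratio of H3-3A to H3-3B of -1.94 (SD 0.03, adjusted p = 3.12e-08, lower in 3 of 3 libraries). H3-5, a retrocopy of H3-3B, stood at 51.3 ± 5.29. On GENCODE lengths H3-3B came to 90.4 ± 3.72 and H3-3A to 31.5 ± 1.97. Reads of these genes, of their processed pseudogenes and of H3-5 can be exchanged between near-identical copies, so the split between them is uncertain.

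All 12 chaperone genes of H3.3 and H3.1 were above 1 RPKM, with a median of 20.6 RPKM at the 99.9 percentile. DEK was highest at 347 ± 15.3 RPKM and NASP, a carrier of soluble H3, next at 82.1 ± 3.2. CHAF1A and CHAF1B, subunits of the replication-coupled H3.1 chaperone, stood at 58.3 ± 0.85 and 32.2 ± 0.28, and ASF1A and ASF1B at 19.9 ± 0.89 and 21.0 ± 0.98. No difference in read density was detected between ASF1A and ASF1B on the deposited widths (log2 ratio -0.07, SD 0.06, adjusted p = 0.147), while on GENCODE lengths ASF1A was higher (log2 ratio 0.33, adjusted p = 0.000325). ATRX (Entrez gene 546), the remodeller that works with DAXX, stood at 30.6 ± 1.07, and HIRA, the chaperone of H3.3 in active genes, at 10.9 ± 0.05. On the deposited gene width DAXX (Entrez gene 1616) was near the bottom of the list at 5.24 ± 0.16, above UBN2 at 3.89 ± 0.41. On GENCODE lengths DAXX came to 24.8 ± 0.78, below only DEK at 229, NASP at 71.0 and CHAF1A at 45.3 among the 12 genes.

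The order of DAXX and its partners depended on the gene length. With the deposited widths the log2 ratio of DAXX was -2.55 to ATRX (SD 0.02, adjusted p = 1.67e-08) and -1.06 to HIRA (SD 0.04, adjusted p = 5.91e-07), lower in 3 of 3 libraries each. The deposited width of DAXX is 14609 bases, 4.74 times its GENCODE exon length of 3084, so those ratios and p-values rest on that width. With GENCODE lengths DAXX came to 24.8 ± 0.78 RPKM, ATRX to 18.0 ± 0.63 and HIRA to 12.5 ± 0.06. DAXX was then above ATRX by 0.47 (adjusted p = 2.13e-05) and above HIRA by 0.99 (adjusted p = 8.71e-07) on the log2 scale. The order of DAXX and ATRX turned on the ATRX length too, 19266 bases on GENCODE against a deposited width of 11307. DAXX on its GENCODE length, at 24.8 RPKM, lay below ATRX on its deposited width, at 30.6. The p-values hold none of this uncertainty in length. DAXX was below CHAF1A under both lengths, with log2 ratios of -3.48 (SD 0.07, adjusted p = 1.38e-08) and -0.87. The number of reads was 9209 for DAXX, 6447 for HIRA and 41639 for ATRX.

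**Figure D2:**
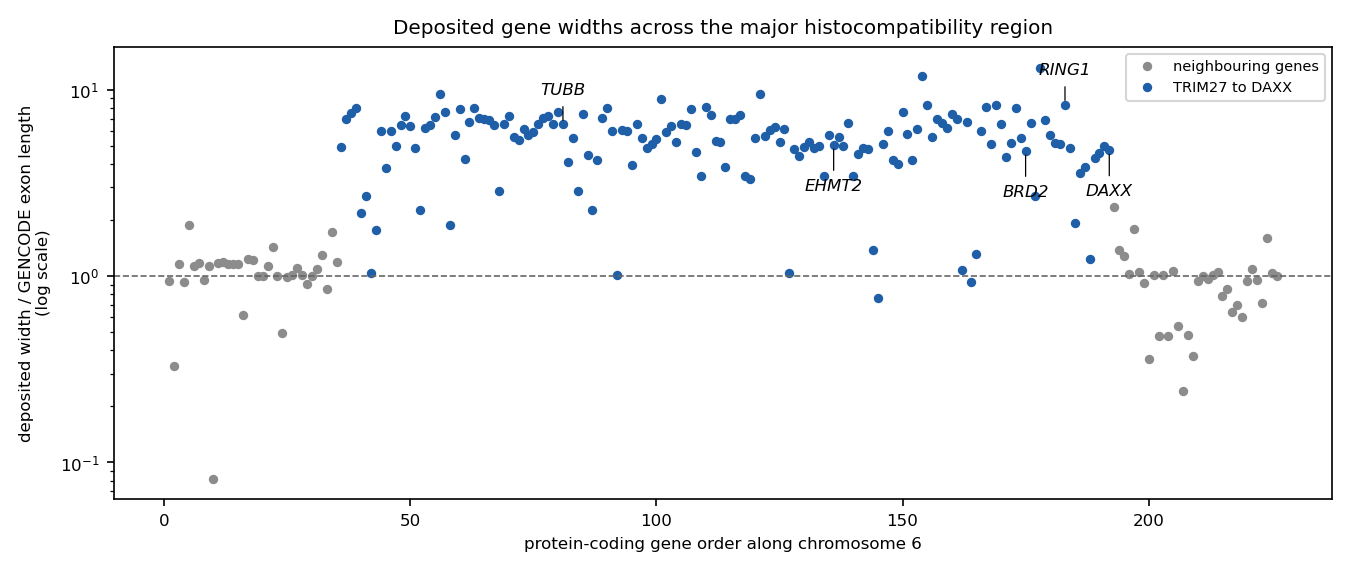
Deposited gene width over GENCODE exon length, on a log axis, for protein-coding genes in their order along chromosome 6, from TRIM27 to DAXX (blue, 157 genes) and on either side (grey, 69 genes). The blue genes have a median ratio of 5.62 and the grey genes of 1.01; DAXX stands at 4.74 and RING1 at 8.33.

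Among genes of PML bodies, the nuclear bodies in which DAXX is found, and of the SUMO pathway, 19 of 20 were above 1 RPKM, with a median of 17.4 RPKM at the 99.9 percentile. On the deposited widths SUMO2 was highest at 270 ± 70.3 RPKM and the SUMO-activating enzyme gene SAE1 next at 155 ± 7.9. On GENCODE lengths SUMO2 came to 85.3 ± 22.2, below SAE1 at 127 and UBA2 at 92.6. PML itself stood at 0.986 ± 0.054 and could not be placed on either side of the level (adjusted p = 0.74). All 15 genes of the H3K9 methylation and HP1 list were above the level. The HP1 genes CBX3 and CBX1 were highest at 121 ± 0.69 and 117 ± 5.5 RPKM, with no difference detected between them on the deposited widths (log2 ratio of CBX1 to CBX3 -0.05, SD 0.07, adjusted p = 0.263). On GENCODE lengths CBX1 at 101 ± 4.7 exceeded CBX3 at 64.1 ± 0.36 (log2 ratio 0.66, adjusted p = 9.8e-06). EHMT2, which encodes the H3K9 methyltransferase G9a, was lowest at 2.05 ± 0.08 on its deposited width and came to 10.4 ± 0.43 on its GENCODE length.

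Of the 57 pairs of paralogs and complex members, 51 differed in read density, 33 of them by more than 2-fold. On GENCODE lengths 46 of the 51 kept their direction and their call. Among these 51 the log2 ratio changed sign in 5 pairs, which were DAXX with ATRX, DAXX with HIRA, PCGF5 with PCGF6, PHF1 with PHF19, and PIAS1 with PIAS3. For PHF1 with PHF19 and PIAS1 with PIAS3 the ratio on GENCODE lengths no longer differed from 0 (adjusted p = 0.431 and 0.31). The 6 pairs with no difference detected on the deposited widths all differed on GENCODE lengths, and ASF1A with ASF1B, CBX1 with CBX3 and PIAS2 with PIAS3 changed sign as well.

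The HOX clusters, classical Polycomb targets, were transcribed in part. Of their 39 genes 24 were above 1 RPKM, 13 were below and 2, HOXA3 at 0.942 ± 0.098 and HOXC5 at 0.904 ± 0.028, could not be placed. Over all genes tested 52.5% were above the level, and over protein-coding genes 58.7%. The HOX share cannot show whether the clusters were repressed, because the genes it is set against include those without a read. The medians of HOXA, HOXB, HOXC and HOXD were 1.31, 2.24, 1.82 and 3.41 RPKM, and 1.07, 1.61, 1.53 and 1.63 RPKM on GENCODE lengths. On the deposited widths the medians lay at the 60.8, 70.0, 70.2 and 84.1 percentiles of random lists. Without length matching they lay at the 46.4, 55.1, 53.5 and 68.0 percentiles. In HOXA 6 of 11 genes were above, led by HOXA5 at 5.40 ± 0.79 RPKM and HOXA13 at 3.96 ± 0.34, while HOXA10 at 0.153 ± 0.030 was lowest. In HOXB 6 of 10 were above, with HOXB7 at 16.0 ± 1.7 and HOXB9 at 10.8 ± 0.58, HOXB5 at 0.126 ± 0.028 and no read from HOXB1, which allowed up to 0.0246 RPKM. In HOXC 6 of 9 were above, with HOXC9 at 10.6 ± 0.22 and HOXC4 at 3.03 ± 0.34, HOXC11 at 0.314 ± 0.045 and no read from HOXC12, which allowed up to 0.0294 RPKM. In HOXD 6 of 9 were above, with HOXD13 at 12.7 ± 0.85 and HOXD10 at 10.7 ± 0.86, HOXD12 at 0.123 ± 0.077 and HOXD1 at 0.0843 ± 0.039. The number of HOXA genes above the level was 3 with the deposited library sizes or RPKM, 4 with GENCODE lengths and 2 at a level of 2 RPKM, and that of HOXC genes was 5 with GENCODE lengths. Neighbouring HOX genes overlap antisense and readthrough transcripts, and the strand setting of the counting is not given in the sources used here.

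**Figure D3:**
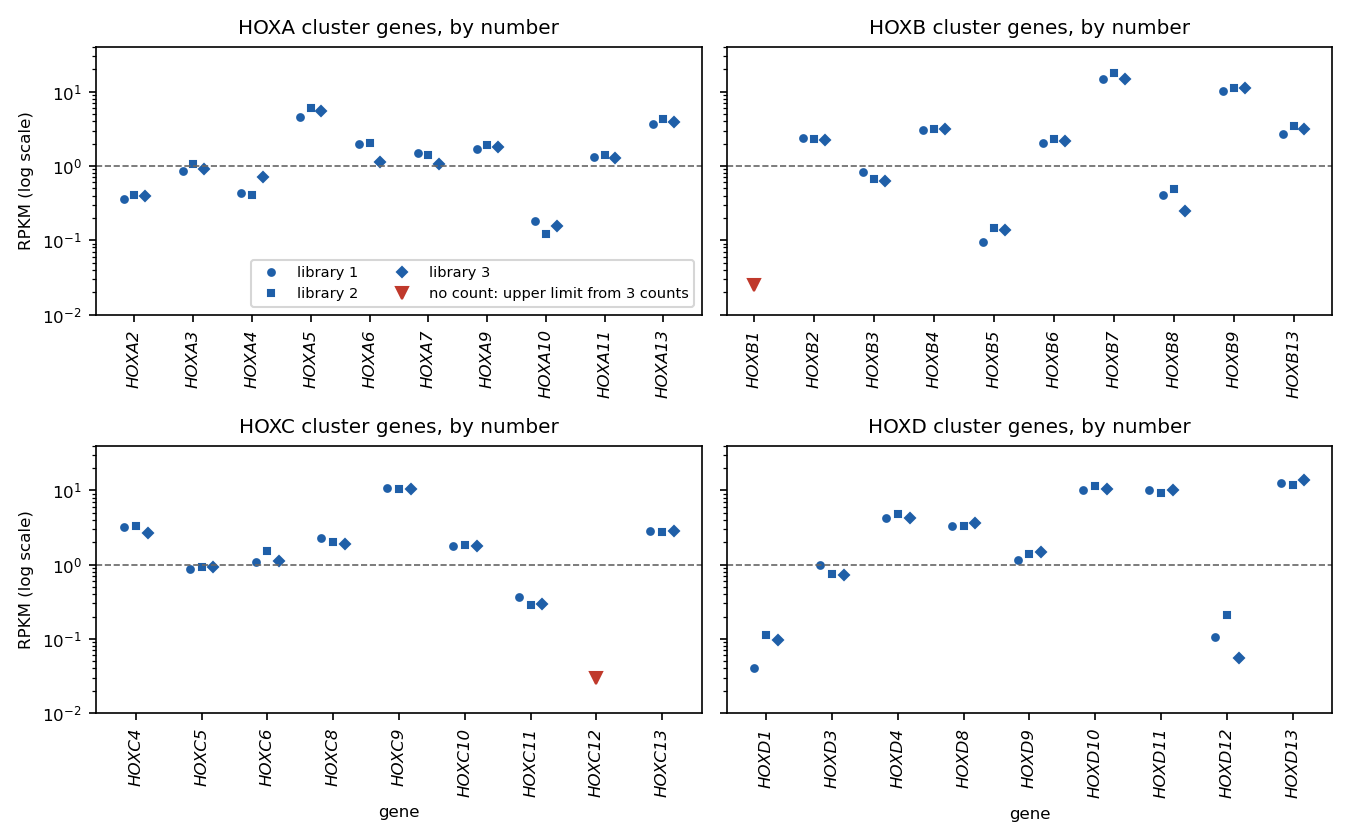
RPKM on a log axis for reported genes of the 4 HOX clusters in 3 libraries (blue points); red triangles mark genes without a read at the upper limit that 3 counts over the libraries would give, and the dashed line is 1 RPKM. High and low genes stand side by side in each cluster, for example HOXB7 at 16.0 RPKM next to HOXB8 at 0.383.

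Developmental transcription factors, many of which are Polycomb targets, were above the level in part, with 37 of 73 above 1 RPKM, 34 below and 2, GATA3 and NKX2-1, not placed. The share above was 52.5% over all genes tested and 58.7% over protein-coding genes. The median of the developmental factors was 1.26 RPKM, at the 28.9 percentile of random lists, and 0.773 RPKM on GENCODE lengths, where 34 were above. MSX1 at 16.9 ± 1.0 RPKM and SOX2, a factor of neural and pluripotent cells, at 13.4 ± 0.49 were highest. The erythroid factor GATA1 had no read, which allowed up to 0.0169 RPKM. Imprinted genes were above the level in 6 of 18 cases, with GNAS at 47.8 ± 2.2 and GRB10 at 11.2 ± 0.37 RPKM, and 11 were below; on GENCODE lengths 5 were above. NDN and ZIM2 had no read, which allowed up to 0.0132 and 0.0103 RPKM.

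Lineage markers gave a mixed picture for this line. Of the kidney epithelial markers 2 of 16 were above 1 RPKM, the simple epithelial keratin genes KRT8 at 262 ± 7.8 and KRT18 at 239 ± 6.8 RPKM, or 86.1 ± 2.56 and 142 ± 4.03 on GENCODE lengths, while CDH16 and SLC34A1 had no read (limits 0.00846 and 0.00722 RPKM). Neuronal markers were above the level in 6 of 16 cases and below in 9. The neurofilament gene NEFL was highest at 55.6 ± 2.9 RPKM and NCAM1 next at 4.52 ± 0.45, and STMN2 and ELAVL4 had no read (limits 0.0104 and 0.0092 RPKM). None of the 14 adrenal and chromaffin markers was above the level under edgeR's test or any alternative, and all 14 were below it, with CHGB highest at 0.267 ± 0.057 and no read from DBH. Of the mesenchymal markers 7 of 12 were above, with the intermediate filament gene VIM at 237 ± 6.4 (98.2 ± 2.66 on its GENCODE length) and the N-cadherin gene CDH2 at 44.2 ± 0.58, while COL1A2 at 0.0110 ± 0.0059 and DCN at 0.00381 ± 0.0066 were lowest. All 16 markers of blood, endothelium and liver were below the level, with HBB highest at 0.588 ± 0.41 and no read from PTPRC or TTR.

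All 18 S phase genes were above 1 RPKM, with a median of 77.9 RPKM, from RRM1 at 265 ± 13 and PCNA at 197 ± 6.4 to E2F1 at 11.2 ± 0.32 and CDT1 at 8.67 ± 0.16. All 12 p53 target genes were above it, led by MDM2 at 120 ± 2.7 and CDKN1A at 29.4 ± 1.4, with FAS at 5.66 ± 0.15 and TP53INP1 at 3.13 ± 0.34 lowest. Of the immediate early and heat shock genes 12 of 16 were above, with the chaperone genes HSPA8 at 806 ± 36.9 and HSP90AA1 at 558 ± 27.1, while EGR1, FOS, FOSB at 0.178 ± 0.051 and EGR2 at 0.109 ± 0.008 were below. On GENCODE lengths HSPA8 at 476 and HSP90AA1 at 477 lay under HSPA1B at 1015 and HSPA1A at 753. Interferon-induced genes were above in 7 of 13 cases, with IFI6 at 7.13 ± 0.21, and OAS2 stood at 0.00402 ± 0.0037 while OAS1 had no read (limit 0.00994 RPKM).

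All 20 housekeeping genes were above 1 RPKM with a median of 147 RPKM, with EEF2 at 791 ± 29 and GUSB at 10.5 ± 0.46. Ribosomal protein genes were above in 78 of 80 cases with a median of 254 RPKM, or 93.7 RPKM on GENCODE lengths, and the exceptions were RPL3L at 0.393 ± 0.148 and RPL10L at 0.0783 ± 0.079, copies of limited tissue range. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail and are kept by a total RNA library, were above in 50 of 66 cases with a median of 103 RPKM. H4C6 had 1 read in all and H4C7 none. Numbered zinc finger genes were above in 398 of 470 cases (379 on GENCODE lengths) with a median of 5.41 RPKM, led by ZNF146 at 106 ± 3.2 and ZNF664 at 83.6 ± 2.8, and ZNF366 and ZNF683 had no read. All 7 long nuclear and small structural noncoding RNA genes were above, from RMRP and RPPH1 to GAS5 at 34.9 ± 3.6 and NEAT1 at 12.5 ± 2.1. Counts adjusted over the list alone were the same as those over all genes in each of the 31 lists.

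The libraries differed from one another beyond counting noise. Of 15138 genes with a mean of at least 10 reads, 4513 (29.8%) differed between libraries, and the mean chi-square per gene was 14.3 against 2 expected from counting alone. The size of the differences was small, with a median SD of log2 CPM of 0.07 and a common biological coefficient of variation of 4.89%. Each pair of libraries differed, in 3482 genes for libraries 1 and 2, 2281 for libraries 1 and 3, and 2409 for libraries 2 and 3, so no pair agreed within sampling noise, which does not tell separate cultures from repeats of 1 preparation. Small nucleolar RNA genes made up 7 of the 10 most variable genes. SNORA24 stood at 83.2, 270 and 393 CPM in libraries 1, 2 and 3, SNORD105B at 0.430, 2.99 and 2.56, SNORD41 at 0.544, 1.98 and 2.29, and SNORD33 at 0.831, 1.74 and 3.09. SNORD29 was at 2.66, 8.54 and 6.26 CPM, SNORD55 at 2.41, 6.83 and 6.13, and SNORA71D at 2.15, 2.87 and 6.29. Their class took 0.0666, 0.0905 and 0.122% of the counts, and 0.0583, 0.0635 and 0.0833% without SNORA24. The other genes of this group were the mitochondrial-like pseudogenes MTRNR2L8 at 0.630, 0.507 and 3.93 CPM and MTRNR2L2 at 1.43, 1.26 and 5.30, and the globin gene HBD at 1.26, 1.26 and 3.2. The number of genes that differed fell to 2409 without library 1 and to 2281 without library 2.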

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

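GENCODE exon lengths and the deposited library sizes were chosen after seeing the data; the other alternatives were planned. The counts of all genes and of all list members above 1 RPKM stayed within 1.5 times of the reported ones under every alternative, from 10558 genes at a level of 2 RPKM to 12858 at 0.5 RPKM. The count below 1 RPKM did so too, except with the DESeq2 Wald test, which placed 6549 genes below; it gave no adjusted p to 3408 genes without a read, which edgeR had placed below. Single lists moved further at 2 RPKM, where 21 developmental factors, 3 HOXC and 3 imprinted genes were above. Pairs that differed ranged from 49 to 55. The 5 lists with a median under the 5th percentile of random lists, a limit set after seeing the data, became 3 without length matching, where neuronal markers moved to the 8.50 and imprinted genes to the 16.2 percentile. The coefficient of variation was 4.26 to 5.80% when each library was left out, and the number of genes that differed between libraries was 2281 to 3482, from tests of 2 libraries in place of 3. CBX7, below 1 RPKM, lay at a log2 of 0.092 over a level of 0.5 RPKM. RING1 on its deposited width lay at -0.44 relative to 1 RPKM, and below it, with limma on deposited RPKM at either pseudocount and with the deposited library sizes, and at -0.90 relative to 2 RPKM; without library 3 it lay at 0.14 and was above, as were all 8 RING-list genes. Without length scaling the log2 ratio was 0.51 for DAXX to HIRA and 0.46 for ASF1A to ASF1B, since the wider gene of a pair then gains. On GENCODE lengths it was 0.47 for DAXX to ATRX, 0.99 for DAXX to HIRA and 0.33 for ASF1A to ASF1B, a pair that then differed, since the lengths themselves differ. Over single genes, pairs, lists and totals, 1006 values under the settings fixed beforehand and 169 under added ones kept their direction and their side of the threshold or moved little. The settings fixed beforehand also moved 23 values, reversed 6, and ended 3 calls and made 2, and added ones moved 3, reversed 4 and made 1 call. No paired analysis was possible because there was 1 group. Depth limited mainly short genes, of which 1217 miRNA genes left 566 that could be tested.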

Other observations

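Of the tests below, those of expressed genes in the chromosome 6 region, of the recovery of short transcripts and of GC content were planned before their results were seen; the others, the bounds of the region from TRIM27 to DAXX, the interval on short transcripts, which left them open, and the limit and interval for GC content were chosen after.

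Heat shock and other genes near DAXX carried the same large widths. On the deposited width HSPA1A stood at 154 ± 13 RPKM and HSPA1B at 203 ± 16, and on GENCODE lengths at 753 and 1015, although reads of these near-identical copies can be exchanged. TUBB, a tubulin gene used as a reference, moved from 66.8 to 435 RPKM and IER3 from 5.15 to 28.3. Library 3 held more reads of 3 mitochondrial-like pseudogenes and of the globin genes HBD and HBB than the others. The counts in libraries 1, 2 and 3 were 22, 21 and 172 for MTRNR2L8, 50, 52 and 232 for MTRNR2L2, 7, 5 and 80 for MTRNR2L1, 44, 52 and 140 for HBD and 7, 10 and 29 for HBB. Library 3 was also the deepest. Scaled for depth, MTRNR2L1 stood at 0.201, 0.121 and 1.83 CPM and HBB at 0.201, 0.241 and 0.663 CPM.

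Genes of the major histocompatibility region on chromosome 6, among them DAXX, RING1, EHMT2 and BRD2, had low deposited RPKM for their reads. The median deposited width was 5.62 times the GENCODE exon length over 157 protein-coding genes of the region, 1.01 times over 69 neighbours and 0.832 times elsewhere, which is consistent with a width that adds up the alternate copies of this region in hg19. A loss of reads to several mapping places stays open, because on GENCODE lengths all protein-coding genes of the region had 0.783 times the median RPKM of those elsewhere, with a 95% bootstrap interval of 0.178 to 2.04 on both sides of the limit of 0.67. The test planned beforehand gave 1.21 (interval 0.846 to 1.71), above that limit, but it kept only genes over 1 RPKM, 83 of 157 in the region and 10702 of 18599 elsewhere, and so left out any gene that lost its reads. For a DAXX transcript scarcer than that of HIRA, the log2 ratio of DAXX to HIRA was -1.06 on the deposited widths and 0.99 on GENCODE lengths. The test needed 1 sign on both lengths and was chosen after its results were seen. As the ratios differ in sign, its outcome was fixed and it could not decide. The negative value rests on a DAXX width 4.74 times its GENCODE exon length. DAXX had 9209 reads on an exon length of 3084 bases, against 6447 reads on 4299 bases for HIRA. These values argue against a scarcer DAXX transcript, as far as the GENCODE lengths hold. The SD of 0.04 over the libraries holds none of the uncertainty in length. On the deposited width 55 of the region's genes were above 1 RPKM and on GENCODE lengths 80 were; no biological explanation was tested for the region as a whole.

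Small nucleolar RNA genes varied most between libraries. Counting noise cannot be the whole cause, because 37.2% of them (58 of 156, 95% interval 29.6 to 45.3%) differed beyond it, against 9.21% of longer genes with the same counts. Uneven recovery of short transcripts in general may contribute and stays open, since the median SD of other genes under 300 bases was 1.08 times that of longer genes (interval 0.956 to 1.52), while 24.7% of them (24 of 97) differed beyond counting noise against 10.2% of longer genes matched to them. For GC content, the ratio for small nucleolar RNAs was 1.62 before and 1.58 after a trend fitted over all genes was removed from each library (interval 1.36 to 2.34). A whole cause would leave a ratio of 1, so this fitted trend does not account for the excess. The removal moved log2 CPM by a median of only 0.0063 for these RNAs, against a median SD of 0.36, and 0.0067 for other genes. A removal that moves so little cannot decide on a GC effect of another form, which stays open. The limit planned beforehand was 1.5, which lies inside that interval. The first version of the counting test, that ratio of 1.62, was replaced after it had been seen, and no biological explanation was tested because the design has 1 group.

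Deposited RPKM was lower than RPKM from the count totals in every library. The deposited library size was 1.45 times the effective size in each, which is consistent with normalization factors taken over a larger set of libraries, although a plain constant would give the same ratio. A denominator of all mapped reads was not supported, because the ratio varied over the libraries by only 2.06e-08 of its mean.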
